A study of Homo sapiens with 4 samples.

How the data were processed

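mRNA sequencing of BCPAP thyroid cancer cells gave 4 libraries: 2 controls and 2 METTL3 knockdown libraries, from colony 1 and colony 3. Per the labels' protocols, total RNA was treated with DNase and libraries were made with an mRNA kit, random priming and PCR. Per the submitters' processing notes, Trim Galore and HISAT2 were used, and the builds mm10 and hg38 are both named; the cells are human. The quantification tool, the expression unit, the scaling and the rule by which genes were chosen are not given in the sources used here.

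The authors deposited a score per gene and library: row z-scores for 4842 Ensembl gene identifiers. For 4839 genes the 4 values have mean 0 and population SD 1 within a tolerance of 1e-09; 3 mitochondrial tRNA genes are 0 in every library. Levels, fold changes, counts and depth cannot be had from such scores, so the precision per library is unknown, and no filter on low values or pseudocount applies. The planned tests assumed counts or normalized expression values, and were replaced, once the unit was known, by a test that fits scores. Because 98.4% of genes separate the groups, against 33.3% by chance, the table looks selected for a group difference; adjusted p-values therefore cover the listed genes and not the transcriptome.

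A linear model with 2 groups was fitted per gene with limma 3.58.1 in R 4.3.3, with the ordinary statistic of each gene and no variance moderation, on 2 residual degrees of freedom. The p of this model does not depend on the scaling of a gene's values by its own SD. It was Benjamini-Hochberg adjusted over 4833 genes, with 6 genes left untested because their values did not differ within groups; genes were called at an adjusted p under 0.05. A model with 3 groups (control, colony 1, colony 3) had 1 residual degree of freedom and left out genes with identical control values. Gene lists with at least 3 members in the table were tested with limma camera on ranks with a preset correlation of 0.01. Their p was adjusted over 22 lists. Camera with an estimated correlation and fry stand beside it. The former rests on the 2 residual degrees of freedom, which limits how small its p can be. On simulated scores for 4839 genes in this comparison, 4.98% of unchanged genes had an unadjusted p under 0.05. So did 99% of genes changed by 10 SD and 100% of those changed by 50 SD. Of random lists of unchanged genes, 0.5% had a camera p under 0.05. The simulated genes were independent, mostly unchanged and not selected, whereas this table looks selected. These shares therefore check the code and give no error rates for this table.

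Symbols were matched by identifier for 4382 genes, and coordinates, gene types and transcripts came from GENCODE release 29 (GRCh38), which held 4748 of the identifiers; coordinates are those of this annotation, and the one the authors used is not given in the sources used here. The counting is not stated to use strand, so overlapping and antisense genes are uncertain. GC content is that of the longest coding transcript. Random lists (10000) were matched on GC decile, and their p is a two-sided permutation p. They take genes as independent, so any correlation between members of a list is ignored.

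The lists, the groups, the choice of list tests and the rule for naming genes were fixed before the data were examined. The test per gene was adapted to scores afterwards, and the list tests were then run on scores. The plan did not name the use of ranks in camera. The rule names METTL3, METTL14, WTAP and CD70; the 12 largest positive and negative differences among called genes whose groups do not overlap; up to 4 called members per direction of each list, or 2 with the smallest adjusted p where none was called; and the 5 largest differences in each direction between colonies. It was applied to score differences, without its floor on expression and leaving out genes with no symbol, and 135 genes met its first 3 parts; the text names some of them, and some are not reported here. The mitochondrially encoded, ribosomal protein and histone lists were fixed as checks of library quality. Of the fixed lists, the list of mitochondrially encoded protein-coding genes had no member in the table, and the thyroid differentiation, immune cell and endothelial lists had too few for a test. Alternatives were quantile normalization, moderated limma with and without robust estimation, leaving out each library, an adjusted p under 0.1, other list tests and other pairings of colonies with controls. Moderated limma without robust estimation, GC matching, protein-coding genes alone and 10 gene families were added after the data were seen.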

Results

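The transcriptome of BCPAP cells, an established line from a papillary thyroid carcinoma, was measured by mRNA sequencing in 4 libraries. METTL3, the catalytic subunit of the complex that writes N6-methyladenosine (m6A) on mRNA, was knocked down in 2 of them, and the other 2 were controls. The knockdown libraries came from colony 1 and colony 3, with 1 library each, so the spread within the knockdown group includes any difference between colonies. The table held 4842 genes as z-scores, in which each gene's 4 values are centred on 0 and divided by their SD. Such scores give the direction of a difference and how tightly the libraries of a group lie together, but neither expression levels nor fold changes. A difference between the 2 group means is bounded at 2, a value approached when the spread within groups is small beside the gap between them. The depth of the libraries is unknown, and the labels do not say whether the libraries of a group came from separate cultures, so p-values measure the spread between these libraries.

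The first question was whether the targeted gene followed the labels. METTL3 (ENSG00000165819, GRCh38 chromosome 14, 21498133 to 21511375, minus strand, protein coding) scored -1.02 in colony 1 and -0.981 in colony 3, against 0.925 in control 1 and 1.07 in control 2. Its mean was -0.999 ± 0.0251 (SD, n = 2) after knockdown and 0.999 ± 0.104 (SD, n = 2) in controls. METTL3 fell by 2.00 ± 0.0758 (SE), with an adjusted p of 0.0102 in the limma linear model, a call that was lost when any 1 library was left out. CD70 (ENSG00000125726, chromosome 19, 6583183 to 6604103, minus strand), which encodes the ligand of CD27, a receptor on lymphocytes, rose by 2.00 ± 0.0814 (SE), with scores of 1.08 and 0.921 in the colonies and -1.02 and -0.972 in the controls (adjusted p = 0.0106). METTL14 and WTAP, partners of METTL3 in the m6A writer complex, were not found in the table by symbol, so their direction is unknown.

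**Figure D1:**
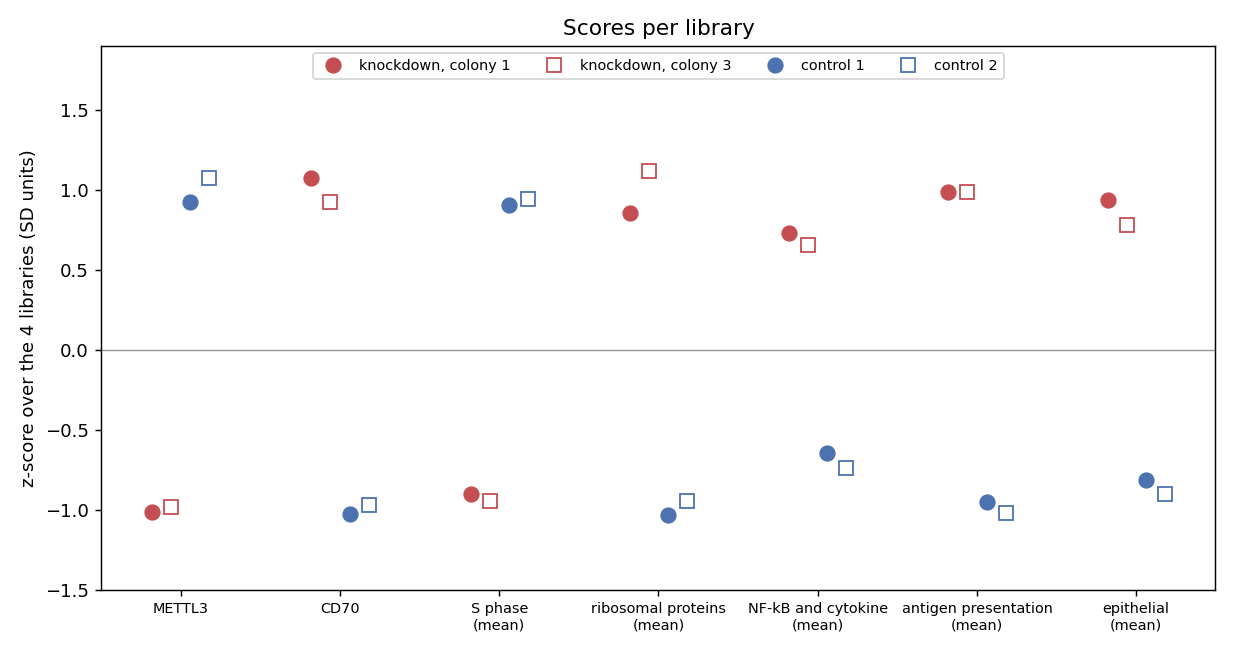
Z-scores (vertical axis, in SD units over the 4 libraries of each gene) of METTL3, CD70 and the mean of 5 gene lists, with 1 point per library, red for knockdown and blue for control. METTL3 and the S phase mean lie below 0 in both colonies and above 0 in both controls, and the other items lie the opposite way.

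Among the m6A machinery, 3 of the 9 writer genes were in the table. RBM15B fell with METTL3 (adjusted p = 0.00845), whereas RBM15, another adaptor of the complex, rose (adjusted p = 0.0145). Of 15 erasers and readers, 3 were in the table: YTHDC2 and HNRNPA2B1 fell (adjusted p = 0.0104 and 0.0116) and IGF2BP2, which binds and stabilises m6A-marked mRNA, rose (adjusted p = 0.0201). All 3 genes of each list changed when adjusted over the list alone, in a table where 76.9% of all genes with values were called. Neither list passed the test against the remaining genes (limma camera, adjusted p = 0.411 for each).

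Across the table, 1770 genes rose and 1949 fell after knockdown, together 76.9% of genes with values (limma, Benjamini-Hochberg adjusted p under 0.05). At that share most members of any list pass, so counts adjusted over a list alone do not set it apart. Both knockdown libraries lay above both controls for 2359 genes and below both for 2403, together 98.4% of the 4839 genes with values, where chance gives 33.3%. The table appears to hold genes already chosen for such a difference, so these counts and adjusted p-values describe the listed genes and do not bound errors over the transcriptome. With 2 libraries against 2, an exact permutation test of a single gene cannot go below p = 0.333. No gene passed once any 1 of the 4 libraries was left out, which leaves 1 residual degree of freedom; 1924 to 2002 genes then had an unadjusted p under 0.05.

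Among tested genes with a symbol, those with the tightest rise included SLC2A3, the glucose transporter GLUT3, with a difference of 2.00 ± 0.00149 (SE, adjusted p = 0.00268). Also among the 12 tightest were IL32, an inflammatory cytokine, TNFAIP3, an inhibitor of NF-kB signalling, PTGES, a prostaglandin E synthase, DNMT3B, a DNA methyltransferase, and TXNIP, a regulator of thioredoxin, each with an adjusted p of 0.00612. The tightest falls included PRDX3, a mitochondrial peroxiredoxin, NOP58, a component of box C/D small nucleolar ribonucleoproteins, HMGA2, a chromatin protein, and CHAF1A, a subunit of a histone chaperone, each also with an adjusted p of 0.00612. A tight difference is not a large one on this scale. RPL13AP12, GOLGA2P10 and KRTAP2-3, also in these groups, have close sequence relatives, and their values are uncertain. RPL13AP12 also had the same score in both controls, so its p rests on the spread of its knockdown values.

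Direction followed the GC content of the transcript. Among 3889 protein-coding genes, the share higher after knockdown was 18.5% (95% Wilson interval 15 to 22.7%) in the decile of lowest GC content and 79.2% (74.9 to 82.9%) in the highest. Libraries within a group differed along the same axis: colony 1 exceeded colony 3 for 42.2% of genes in the lowest decile and 74.9% in the highest, and control 1 exceeded control 2 for 67.1% and 37.2%. Lists that camera called are given with the number of members expected to lie above control from the GC decile of each member. Beside it stands a two-sided permutation p from 10000 random lists matched on GC decile. This p takes genes as independent and ignores correlation between members of a list. Of the tested lists that camera did not call, none passed this permutation test, and the smallest adjusted p among them was 0.116, for fibroblast markers. Counts are over list members in the table, and a table that looks selected may leave out unchanged members. It held 27 of 40 fixed members for S phase, 20 of 35 for NF-kB and cytokine and 12 of 27 for antigen presentation. It held 13 of 33 immune ligands and checkpoints, 15 of 32 epithelial genes, 11 of 20 YAP/TAZ targets and 10 of 25 p53 targets.

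**Figure D2:**
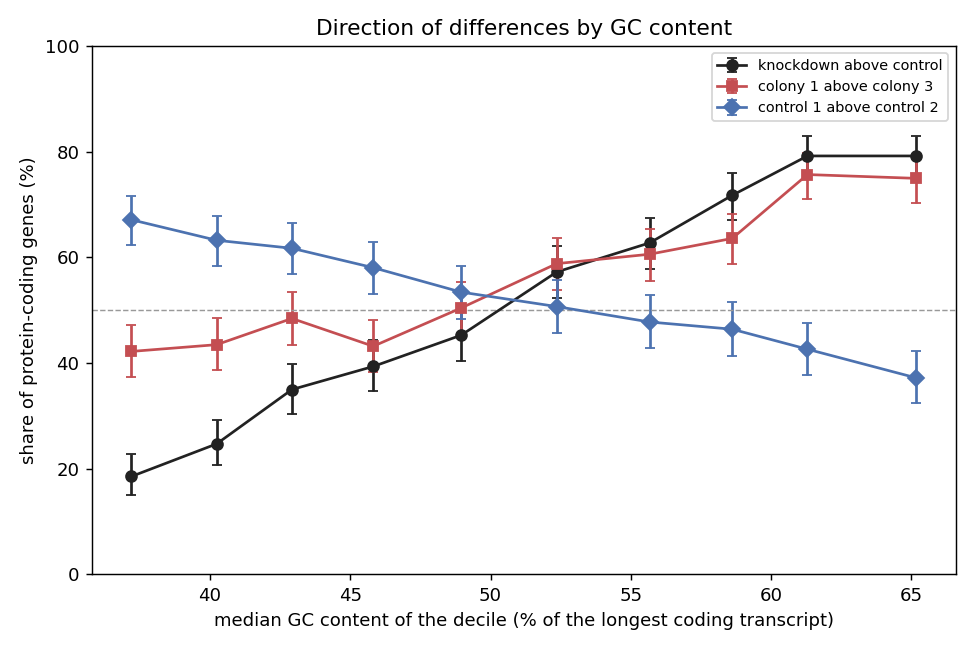
Share of protein-coding genes (vertical axis, %) for which knockdown exceeded control, colony 1 exceeded colony 3 or control 1 exceeded control 2, by the median GC content of each decile (horizontal axis, %), with 95% Wilson intervals. The share with knockdown above control goes from 18.5% to 79.2%, and both comparisons within groups also change with GC content.

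Genes of S phase had the smallest camera p of the 22 lists tested. Of the 27 members in the table, 26 fell and 1 rose, and all 27 passed when adjusted over the list alone (limma camera, adjusted p = 3.5e-07; adjusted p = 0.448 with an estimated correlation). The members that fell included the replicative helicase subunits MCM2 and MCM3 (adjusted p = 0.00845 and 0.00699), the histone chaperone subunit CHAF1A and the transcription factor E2F1 (adjusted p = 0.00798). CDT1, which licenses replication origins, rose by 1.94 ± 0.342 (SE, adjusted p = 0.0411). For S phase 1 member lay above control where GC content gave 13 (GC-matched adjusted permutation p = 0.0011). The G2/M list had 3 genes up and 8 down among 11, all 11 changed when adjusted over the list alone, and did not pass against the other genes (adjusted p = 0.21). FOXM1 and CENPF, of mitosis, fell (adjusted p = 0.0108 and 0.0114) and the kinesin KIF20A rose (adjusted p = 0.00908).

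Ribosomal protein genes, a list fixed as a check of library quality, lay on the other side. A difference in library quality between the groups cannot be told apart from an effect of the knockdown here. All 21 in the table were higher in both knockdown libraries than in both controls, and 20 of them rose, the same number as when adjusted over the list alone (camera adjusted p = 3.19e-05; adjusted p = 0.577 with an estimated correlation). RPL8 and RPL7A rose with adjusted p of 0.00865 and 0.00932, and RPL35A, with a difference of 1.88 ± 0.48 (SE), did not pass (adjusted p = 0.0707); it is named as the exception, after its values were seen. GC content gave 12 members above control, against 21 (GC-matched adjusted permutation p = 0.0011). Many ribosomal protein genes have processed pseudogenes that can share their reads.

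Inflammatory and immune genes were mostly higher. In the NF-kB and cytokine list, 16 of 20 genes rose, 2 fell and 2 did not pass, with 18 changed when adjusted over the list alone (camera adjusted p = 0.0014; adjusted p = 0.448 with an estimated correlation). IL32, TNFAIP3 and NFKB2, a subunit of NF-kB, rose (adjusted p = 0.00842 for NFKB2), whereas the cytokines IL1B and CXCL5 fell (adjusted p = 0.0106 and 0.0178). Of the 20, 17 lay above control where GC content gave 10.5 (GC-matched adjusted permutation p = 0.00513). In the antigen presentation list 11 of 12 genes rose and none fell, 11 also when adjusted over the list alone, among them the immunoproteasome subunit PSMB9 and the chaperone CALR (adjusted p = 0.00943 and 0.00924). The list had a camera adjusted p of 0.00161, and an adjusted p = 0.448 with an estimated correlation. All 12 lay above control where GC content gave 8.18, which did not pass (GC-matched adjusted permutation p = 0.0695). Reads can be shared between close paralogs in these lists, and the value of MICA is uncertain for this reason. Of 13 immune ligands and checkpoints, 9 rose, 2 fell and 2 did not pass, with 11 changed when adjusted over the list alone (camera adjusted p = 0.0221; adjusted p = 0.564 with an estimated correlation). CD70, TNFSF9 and MICA rose, and TNFSF15 and the ectonucleotidase NT5E fell (adjusted p = 0.00842 and 0.00862). Of the 13, 11 lay above control where GC content gave 7.24, which did not pass (GC-matched adjusted permutation p = 0.0984). The interferon-stimulated list had 6 genes up and 3 down among the 11 of its 41 members in the table. With 9 changed when adjusted over the list alone, it was not called (camera adjusted p = 0.564).

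Among epithelial genes, 13 of 15 rose, none fell, and 13 changed when adjusted over the list alone (camera adjusted p = 0.00161; adjusted p = 0.448 with an estimated correlation). The keratins KRT80 and KRT7 and the desmosomal protein DSP rose (adjusted p = 0.00842, 0.0097 and 0.0112). Of the 15, 14 lay above control where GC content gave 9.57, which did not pass (GC-matched adjusted permutation p = 0.0695). Mesenchymal genes went both ways, with 9 up, 5 down and 2 not passing among 16 and 14 changed when adjusted over the list alone (adjusted p = 0.339). TGFBI, an extracellular matrix protein, rose (adjusted p = 0.00612) and fibronectin, FN1, fell (adjusted p = 0.00845). Of 11 YAP/TAZ targets, 9 rose and 1 fell, with 10 changed when adjusted over the list alone (camera adjusted p = 0.00677; adjusted p = 0.448 with an estimated correlation), including the matricellular protein CCN1 (adjusted p = 0.00929). GC content gave 5.65 of the 11 above control, against 10 (GC-matched adjusted permutation p = 0.0431). Of 10 p53 targets, 8 rose and 1 fell, and 10 changed when adjusted over the list alone (camera adjusted p = 0.0221; adjusted p = 0.448 with an estimated correlation). PLK2 and PLK3, polo-like kinases, rose (adjusted p = 0.00685 and 0.00731), and TP53I3 fell (adjusted p = 0.0107). GC content gave 5.33 of the 10 above control, against 9 (GC-matched adjusted permutation p = 0.0431).

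The remaining lists were not called as groups. Their counts too are over members in the table, such as 6 of 18 MAPK output genes and 5 of 32 hypoxia and glycolysis genes. Of 6 MAPK output genes, 5 fell, among them the ERK phosphatase DUSP6 (adjusted p = 0.0132), and the transcription factor MYC rose (adjusted p = 0.0119); all 6 changed when adjusted over the list alone, with a camera adjusted p of 0.115. Of 12 immediate early genes, 7 rose and 3 fell, with 10 changed when adjusted over the list alone (camera adjusted p = 0.21). JUNB and DUSP1 rose (adjusted p = 0.00731 and 0.00842), and FOS and EGR1 fell (adjusted p = 0.011 and 0.00908). The thyroid transcription factor NKX2-1, the 1 gene in the table among 20 of thyroid differentiation, rose (adjusted p = 0.00878). It also passed over the list alone, where 1 gene leaves nothing to adjust. In the stress and unfolded protein response list, 5 genes rose, among them the chaperone HSPA5 (adjusted p = 0.00641), and 6 fell, among them CHAC1, a glutathione-degrading enzyme (adjusted p = 0.00637). All 11 changed when adjusted over the list alone (camera adjusted p = 0.976). Of 8 apoptosis regulators 3 rose and 3 fell, 6 when adjusted over the list alone (camera adjusted p = 0.523). Of 4 Wnt targets 2 rose and 1 fell, 3 when adjusted over the list alone (camera adjusted p = 0.622). Of 8 cholesterol synthesis genes 5 rose and 1 fell, 6 when adjusted over the list alone (camera adjusted p = 0.359). Of 5 hypoxia and glycolysis genes 2 rose and 2 fell, 4 when adjusted over the list alone (camera adjusted p = 0.964), and their median difference was negative while camera ranked them upward.

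Markers of other cell types were few. Of 5 fibroblast markers in the table, 3 rose, including THY1 (adjusted p = 0.00842), the same number as when adjusted over the list alone, and the list was not called (adjusted p = 0.21). The endothelial markers CDH5 and ESAM rose (adjusted p = 0.0201 and 0.0357), both also when adjusted over the list alone. CDH5 had the same score, -0.99, in both controls, so its p rests on the spread of its 2 knockdown values. Of 140 genes with identical scores in both controls, 124 were lower there than after knockdown. Of 167 genes identical in both knockdown libraries, 151 were lower there than in controls. Most ties thus lay on the low side, where a floor would put them, but scores alone cannot show a floor. The immune marker CSF1R, with a difference of -1.88 ± 0.477 (SE), did not pass over all genes (adjusted p = 0.0698). It was the 1 immune marker in the table, which leaves nothing to adjust, and 0 changed over that list alone. The 6 genes picked by histone symbols, of which 2 rose and 1 fell (3 when adjusted over the list alone), had a camera adjusted p of 0.411.

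**Figure D3:**
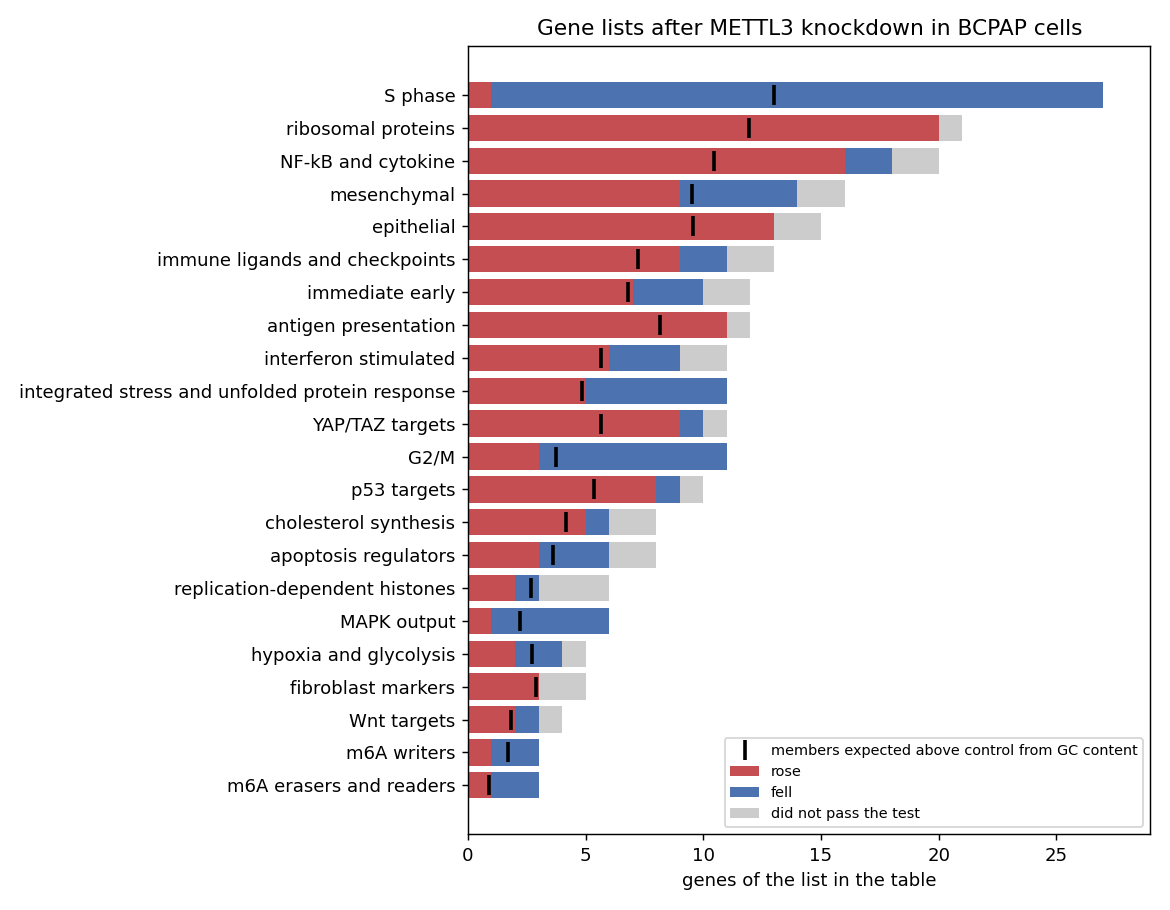
Genes of each list in the table (horizontal axis, number of genes) that rose (red), fell (blue) or did not pass the test (grey) after knockdown. Black ticks give the number of members expected to lie above control, called or not, from the GC content of their transcripts: 13 for S phase, where 1 did.

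The colonies were then compared with the controls and with each other in a model with 3 groups, which compares libraries and assumes that each lone library varies like the controls. Of 4699 genes tested, none passed an adjusted p of 0.05 in limma for colony 1 or colony 3 against control, or between colonies. At an unadjusted p under 0.05 there were 2002, 1932 and 242 genes, the last being 5.15% of those tested. With quantile normalization 4 genes passed for each colony against control and 0 between colonies. Differences of the colonies from controls that shared no library had a Pearson correlation of 0.93 across genes (covariance 3.59; simulated unchanged libraries gave a covariance of -0.000193). With both controls shared it was 0.965, where simulated unchanged libraries gave 0.334, and the covariance was 3.66 against a simulated 0.668. Genes are not independent replicates, and a table of genes chosen for a group difference gives such a correlation by its making. Among genes with a symbol, the 5 with the greatest score difference in each direction between colonies were C6orf132, ARHGAP45, PRPF40B, FMN1 and TENM4, higher in colony 1, and ZNF404, VAMP1, CHD9, EPHA1 and ZNF704, higher in colony 3, with differences of 2.3 to 2.76 in size for the latter. None was called.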

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

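Both colonies lay outside the range of the controls, on opposite sides, for 12 genes, 0.248% of the 4839 with values. Chance gives 16.7%, but a table that looks selected for a difference between knockdown and control would leave out such genes, so the low share says nothing about how alike the colonies are. For each of these genes one colony moved up and the other down against the controls. Of the genes with a symbol named for their difference between colonies, 8 were among them. Colony 3 minus colony 1 was -2.78 for C6orf132, -2.67 for ARHGAP45, -2.57 for PRPF40B, -2.55 for FMN1 and -2.46 for TENM4. It was 2.76 for ZNF404, 2.68 for VAMP1 and 2.49 for CHD9. In the limma model with 3 groups, which has 1 residual degree of freedom, no gene passed between colonies (smallest adjusted p 0.93; 242 genes at an unadjusted p under 0.05).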

How the results depend on the processing

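Moderated limma without robust estimation, protein-coding genes alone and GC-matched lists were chosen after the data were seen. The first 2 of these, robust limma, quantile normalization and an adjusted p under 0.1 kept the counts of higher and lower genes within 1.5 times. Without any 1 of the 4 libraries, 0 genes rose and 0 fell in limma (1924 to 2002 at an unadjusted p under 0.05), and the METTL3 knockdown minus control score was -2.07 to -1.92, no longer past the threshold; such fits have fewer samples and assume that the lone library varies like the other group. Of 22 lists, 8 were called by camera and 0 by camera with an estimated correlation, which rests on 2 residual degrees of freedom. Fry, which does not compare a list with other genes, called 19. Against random lists matched on GC content, 5 passed. Under quantile normalization all 22 lists kept their side of the threshold; leaving out control 2 brought the fibroblast list past it, and leaving out another library moved none. With quantile normalization 4 genes passed for colony 1 against control and 4 for colony 3, against 0; the cause was not tested. The correlation of colony differences was 0.93 with crossed controls and 0.965 with both controls shared. Filters on low values, pseudocounts, a fold of at least 2, count-based scalings and tests, limma's trend and removing gene classes from library totals were not run, because scores carry no levels. No paired analysis was possible because the labels give no pairing between colonies and controls.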

Other observations

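The gene families and the genes named from them, the motif, length and chromosome tests, the sign comparison within groups, the test of a GC bias shared within groups and the matching of gene lists on GC content were chosen after the data were seen. Of 10 SR protein and hnRNP genes, whose products bind and splice pre-mRNA, 9 fell, including SRSF1, SRSF2 and HNRNPU, and SRSF4 rose. Of 10 genes with DDX or DHX symbols, a family picked by symbol and not by helicase type, 9 fell and DDX41 rose. Among the 10, DDX11, DDX12P and DDX12B are near copies of each other and uncertain. Of 16 genes with polymerase subunit symbols, which take in the antisense gene POLR1HASP, 11 fell and 2 rose. Of 12 centrosomal CEP genes 8 fell and 0 rose, and of 148 genes with ZNF symbols, which take in antisense transcripts and pseudogenes, 63 fell and 31 rose. Of 12 genes with CDK symbols 10 rose, including the cyclin-dependent kinase inhibitors CDKN1B, CDKN1C and CDKN2A, and 1, CDK17, fell. All 5 IGF-binding protein genes and all 5 claudin genes in the table rose. Of 8 Notch pathway genes 5 rose and 1, HEY1, fell, and of 18 collagen genes 8 rose and 3 fell. These families were picked from the same data, so their counts are a description; random families matched on GC content were also drawn, but a test on families picked this way decides nothing and is not used here. The number of higher members of each of the 10 families was the same under quantile normalization.

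The rise of the share of higher genes with GC content was not carried by transcript length, since in the length quintile with the smallest gap the share still differed by 39.8 percentage points between the top and bottom tertiles of GC content. Nor did higher genes hold more METTL3 motifs at matched GC content: GGACT sites per kb differed by -0.0486, higher minus lower (permutation p = 0.0393), against -0.0178 for shuffled motifs (0.119) and -0.0308 for GGACT minus shuffled (0.241), while without matching the means were 1.12 in higher and 0.979 in lower genes. The slope on GC content was 10.8 times greater between groups than within them. In this table, which looks selected for a group difference, differences between groups were themselves 9.05 times greater in the median. The bound of 5 set beforehand was therefore wrong and the ratio of slopes decides nothing. Signs were compared next. From the lowest to the highest GC decile, the share with colony 1 above colony 3 changed by 32.8 points. The share with control 1 above control 2 changed by -29.9, against 60.7 between groups. The first passes the bound set for this test by less than its SE of 3.37, and the second misses it. This comparison does not decide the question either, because small differences change sign more easily than large ones. Median differences were 0.215 between colonies and 0.219 between controls, against 1.98 between groups. A GC bias that differs from library to library stays possible for part of the trend, without a test here that decides it. One shared by the libraries of a group (0.879 score units per 10 points of GC content) cannot be told apart from an effect of the knockdown, because no batch is given.

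Random lists matched on GC decile seldom split as unequally as S phase and ribosomal protein genes (adjusted permutation p = 0.0011 each) or NF-kB and cytokine genes (0.00513). The same held for YAP/TAZ targets and p53 targets (0.0431 each). This argues against GC content as the whole reason for their direction only if members move independently. Members can move together, with an estimated correlation of 0.515 for ribosomal proteins and 0.0134 for S phase. No list passed camera with an estimated correlation (smallest adjusted p = 0.448). That test also weakened lists with a negative estimated correlation. For antigen presentation (-0.0476) the unadjusted camera p went from 0.000367 with the preset correlation to 0.0645. The test rests on 2 residual degrees of freedom, so its lack of calls does not show that members move together. For antigen presentation and epithelial genes (0.0695 each) and for immune ligands and checkpoints (0.0984), GC content remains a possible explanation. An effect of METTL3 knockdown stays open for all of them and was not separated from differences between cell colonies.

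Chromosomes 9 and 11 held more higher genes than their GC content gives: 126 of 173 against 97.4 expected, and 184 of 256 against 148 expected. In 10000 permutations of direction within GC deciles, no chromosome lay as far out (family-wise permutation p = 0.0001 for each, the smallest these can give). If genes vary independently, this argues against GC content as the reason. Chromosomes 2 and 7 lay below, at a family-wise permutation p of 0.002 and 0.0188. Of the 8 bins of 20000000 bases with at least 20 genes on both chromosomes, 7 lay above their GC expectation. The lowest of these 8 was -0.102 standard errors from it. Among bins with fewer genes, the first of chromosome 9 lay lower. There 1 of 7 genes was higher, 14.3% against 39.2% expected (-1.49 standard errors). The other bins with fewer genes lay above their expectation. A copy number difference common to both colonies is a candidate explanation, and an effect of the knockdown itself stays open. The bins had been seen before this test was written, the chromosomes were picked for their excess, and scores carry no dosage, so this stays a hypothesis.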
